A study of Homo sapiens with 4 samples.

How the data were processed

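RNA of the human lymphoma line TMD8 was measured on 4 Agilent whole-genome oligonucleotide arrays of the 2-colour kind. On each array the Cy5 channel held RNA of cells with an shRNA against TLR7 or TLR9 and the Cy3 channel held RNA of cells with a control shRNA, per the labels. The dyes were never swapped, so the dye and the knockdown ran the same way on every array. The 4 arrays lay on 1 slide and were read in 1 scan, per the file headers, so array position and group cannot be told apart and no slide or scan batch could be fitted.

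The scanner files hold the mean spot intensity and the median local background intensity of both channels, written by Agilent Feature Extraction 10.1.1.1 and not normalized, per the file headers. The processed intensity in the same files was background-subtracted, detrended over the slide and dye-normalized by linear and lowess fits, per the file headers. Their deposited log10 ratio is that of the processed Cy5 over the processed Cy3 signal and is 0 where both signals were replaced by a surrogate. The authors' series matrix holds log10 ratios, and all of them matched the log10 ratio of processed Cy5 over processed Cy3 signal within 0.0006 on every array. They matched the log10 ratio column of the scanner files for 80.8% to 89.1% of spots, because the matrix keeps the surrogates. The scale and direction of the matrix are therefore known, and no further centring was found. Its column medians were -0.047, -0.033, 0.001 and -0.01 for shTLR7 day 1, shTLR7 day 2, shTLR9 day 1 and shTLR9 day 2.

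From the spot intensities, log2 ratios of Cy5 over Cy3 were computed with limma 3.58.1 in R 4.3.3. The background was corrected with normexp and an offset of 50, and each array was normalized by loess with control spots at weight 0. The offset pulls the ratios of dim genes towards 0, so folds of dim genes are understated. Spots that Feature Extraction marked as non-uniform or population outliers were left out, between 140 and 662 of 43376 spots an array. Of 41000 probes, 29359 were well above background in either channel on at least 2 of the 4 arrays and were kept. XIST, TSIX and genes of the Y chromosome, 129 spots, were left out throughout. Spots of 1 probe and then probes of 1 gene were averaged, which left 21216 genes with a value on all 4 arrays. Probe names were updated through RefSeq accessions in a table of GRCh38.p14 genes. Of the spots, 28671 matched 1 symbol, 1064 matched several and 13641 matched none, and the latter kept the name in the file. Of the genes tested, 14672 carried a current symbol. Among the 2186 genes called under shTLR7 with more than 1 probe, the probes of 189 differed in sign. Probe positions are those of the files, on hg19, and no exon or UTR annotation of that build was used.

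Each shRNA and day is 1 array, so single arrays are given as values with no test. The labels do not say whether the days come from separate transductions, so p-values measure only the spread between these arrays. For the tests, limma's lmFit and eBayes fitted 1 coefficient for each shRNA over its 2 days, with the spread between the days of an shRNA as the error, 2 residual degrees of freedom and a fitted prior worth 6.88. The contrasts were shTLR7 over control, shTLR9 over control, the mean of both, and shTLR9 minus shTLR7. The control is the Cy3 channel and has no replicate, so tests against 0 leave out its own spread. A probe's dye effect that is the same on every array adds to the first 3 contrasts and cancels in shTLR9 minus shTLR7. Day 2 minus day 1 came from an additive model of shRNA and day with 1 residual degree of freedom. P-values were adjusted by Benjamini-Hochberg over genes with a threshold of 0.05. A gene is called 1.5-fold here from a log2 value of 0.58 in size. A level not well above background gave a bound, the brighter mean over the higher of the gene's own dim signal and the lowest signal well above background on each array. These signals were averaged over all probes of the gene, those that missed the detection filter included. For such bounds channels were compared after loess and Aquantile normalization, and they are open to dye bias.

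There were 26 gene lists, fixed before the data were examined. They covered NF-kB target genes, JAK-STAT target genes, the type I interferon response, the Toll-like receptor pathway, B cell receptor signalling, B cell identity, plasma cell differentiation, the unfolded protein response, ATF4 and the amino acid response, MYC targets with ribosome biogenesis, the cell cycle, p53 target genes, the BCL2 family with caspase inhibitors, cholesterol biosynthesis, glycolysis with hypoxia, oxidative phosphorylation, immediate early genes, lymphocyte trafficking with FOXO1 targets, antigen presentation, replication-dependent histones, ribosomal proteins, the RNA interference machinery, housekeeping genes, and markers of T and NK cells, myeloid cells, and epithelial cells and fibroblasts. Each was tested with limma's camera at its preset correlation of 0.01 and again with an estimated correlation, with p-values adjusted over the lists. With an estimated correlation camera tests on the 2 residual degrees of freedom. That setting has little power and cannot show that correlation between genes accounts for a lost call. List medians were also ranked among 10000 random lists of the same size and intensity. A further 7 short lists were written after the values were seen and have no camera test.

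The named genes follow a rule fixed before the data were examined. For shTLR7, shTLR9 and their difference, the rule takes the 10 highest and 10 lowest means among genes past the threshold with the same sign on both days and a real symbol. For the day it takes 5 and 5, and for each list up to 4 members with the largest mean. After the alternatives had been run, the members named per list were cut to 3, and to 2 for the difference, to limit the values to be printed. That left unnamed 4 genes under shTLR9 (BTK, PTPN6, BBC3 and BTG2) whose sign turned with median centring. TLR7 and TLR9 come first. The alternatives were no background subtraction, median centring, Agilent's processed log ratio, the series matrix, scaling between arrays, other filters, the brightest probe, an intensity trend in eBayes, day as a term, leaving out each array, and an estimated correlation in camera. A correction for probe GC content and a floor of 1.5-fold on calls were added after seeing the data. Figures were drawn with matplotlib 3.10.9.

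The steps were tested on simulated data, log ratios of 21216 genes with the fitted spread, in which known genes were changed under shTLR7, under shTLR9 and between the days. For shTLR7 over control, 88.4% of the genes changed by 0.58 were recovered, 98.5% of those changed by 1 and 100% of those changed by 2 on the log2 scale, and 2.05% of the calls were false. For shTLR9 minus shTLR7 the shares were 56.5%, 95.6% and 100%, with 2.94% of calls false. For day 2 minus day 1 they were 68.3%, 100% and 100%, with 5.73% false. With no list shifted, 0 of 78 list tests passed in each of 20 simulations. The simulated genes were independent, which real genes are not. The number of arrays limits the precision.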

Results

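TMD8 is an established cell line of the activated B cell-like subtype of diffuse large B cell lymphoma and carries an oncogenic form of MYD88, the adaptor of Toll-like receptors. The series asked what such cells require of these receptors, and its arrays show which transcripts differed once TLR7 or TLR9, endosomal receptors for nucleic acids, was knocked down. Cells were transduced with retroviruses that express an shRNA under doxycycline. RNA was taken after 24 h (day 1) and 48 h (day 2) of induction and hybridized against RNA of shControl cells of the same day. The data hold 4 arrays, 1 for each shRNA and day, with no replicate array and no dye swap. The labels do not say how many shRNA sequences were used for each target. Off-target effects of an shRNA therefore cannot be told apart from the loss of its target, in either knockdown or in their difference. Cy5 signals were well above background for 66.3% to 78.9% of spots and Cy3 signals for 64.2% to 72.0%. At most 4 spots an array were saturated. Across genes, the log2 ratios of the 2 days correlated with r = 0.82 for shTLR7 and 0.78 for shTLR9, although genes are not independent replicates. All values below are log2 ratios of knockdown over control. Means over the 2 days carry the SE of the limma fit.

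The targeted transcripts were lower on the arrays that bear their shRNA. TLR9 fell to -1.88 on day 1 and -2.10 on day 2 under shTLR9, a mean of -1.99 ± 0.08 (adjusted p = 2.06e-05) that left 25.2% of the control level. Its probe lies on chromosome 3 at 52255221 to 52255280 (hg19). TLR7 fell to -0.89 and -0.78 under shTLR7, a mean of -0.84 ± 0.06 (adjusted p = 4.09e-05). Its probes, on chromosome X at 12906559 to 12906618 and 12908260 to 12908319, gave -0.59 and -1.08, or 66.4% and 47.3% of the control level. The authors' processed values put TLR7 further from 0, at -1.34. The other receptor was also lower under each shRNA, TLR9 at -0.44 under shTLR7 (adjusted p = 0.00217) and TLR7 at -0.25 under shTLR9 (adjusted p = 0.0292), but with median centring neither passed, TLR9 at -0.18 (adjusted p = 0.275) and TLR7 at 0.04. With the authors' processed values TLR9 under shTLR7 had an adjusted p of 0.0536. Each targeted gene was lower under its own shRNA than under the other, by -1.55 for TLR9 (adjusted p = 9.32e-05) and by 0.59 for TLR7 (shTLR9 minus shTLR7, adjusted p = 0.00375). With the authors' processed values neither difference passed (adjusted p = 0.0605 for TLR9 and 0.0754 for TLR7).

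**Figure D1:**
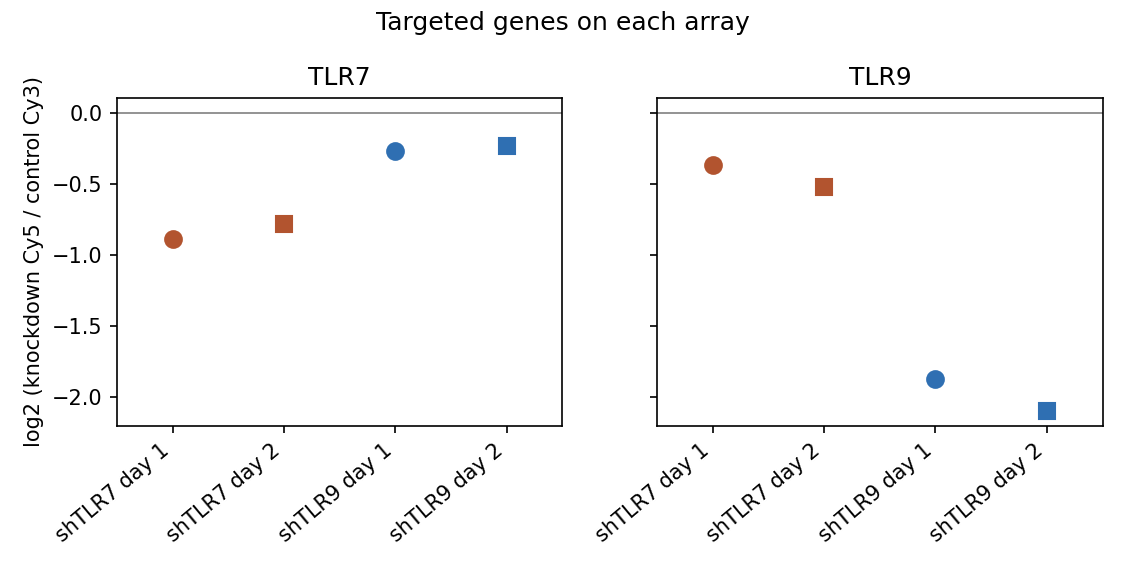
Log2 ratio (knockdown Cy5 over control Cy3, vertical axis) of TLR7 and TLR9 on each of the 4 arrays. Each point is 1 array, circles are day 1 and squares day 2. TLR9 lies at -1.88 and -2.10 on the shTLR9 arrays, and TLR7 at -0.89 and -0.78 on the shTLR7 arrays.

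Among genes with a current symbol, those that rose most under shTLR7 included CYP1A1, a cytochrome P450 induced through the aryl hydrocarbon receptor, ADM, a hypoxia-induced peptide hormone, and H19, an imprinted noncoding RNA. Some transcripts without a current symbol moved further in either direction. CYP1A1 (probe on chromosome 15, 75012562 to 75012621) rose by 2.38 ± 0.08, ADM (chromosome 11, 10328780 to 10328839) by 2.32 ± 0.11 and H19 by 2.31 ± 0.09. KRT80, a keratin, was not well above background in the control and rose at least 2.45-fold. That bound averages all its probes, dim ones included, while the 1 probe kept gave a log2 ratio of 2.59. DHDH rose by 2.29, GDF15, a stress-induced cytokine, by 1.98, SERPINA9, a serpin of germinal centre B cells, by 1.92, GADD45G by 1.89, AKAP9 by 1.74 (0.62 when dim probes were kept) and TXNIP, the thioredoxin-binding protein, by 1.70. POU2AF1, the B cell coactivator of octamer-binding factors, fell to -2.18 ± 0.08. NUAK2, a kinase, fell to -1.83, UCHL1, a deubiquitinase, to -1.80, GZMB, the granule protease granzyme B, to -1.79 and PPDPF to -1.61. DHCR7 (-1.78), SQLE (-1.60) and MVK (-1.53) are enzymes of cholesterol synthesis. PLS3, an actin-bundling protein, was not well above background in the knockdown and fell at least 3.35-fold. CFAP251 stood at -1.74, but its 2 probes gave -2.76 and -0.71. The knockdown signals of NUAK2 and UCHL1 were not well above background on every array, so these genes and PLS3 cannot be ranked against POU2AF1. Adjusted p for these 20 genes ran from 1.07e-06 to 4.74e-05. In all, 7580 of 21216 genes passed, 4012 higher and 3568 lower, and 1132 of them changed at least 1.5-fold, 728 up and 404 down. With median centring 5679 were higher and 722 lower, and at 1.5-fold 2125 and 151. On both days, 494 genes were at least 1.5-fold higher, 255 lower and 8 opposite. Genes 1.5-fold the same way on both days moved from 749 to 2673 with the authors' series matrix values and 1310 with median centring. The authors' series matrix values gave 4862 genes.

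The gene list with the deepest shift under shTLR7 was cholesterol biosynthesis, with 22 of 25 measured members lower, 0 higher and a median of -1.16. ACAT2 fell to -1.51. Of 31 MYC targets and ribosome biogenesis genes, 22 fell and 1 rose (median -0.30), with MRTO4 at -1.37, NOP16 at -0.64 and EIF4A1 at -0.62. With median centring the median of this list shrank to -0.00987 and the list no longer passed (adjusted p = 0.052), nor did NOP16 (adjusted p = 0.270) and EIF4A1 (adjusted p = 0.240). Of 15 JAK-STAT target genes, 9 fell and 2 rose (median -0.22), with SOCS3 at -0.82 and OSM at -0.51 but IL10 at 0.63. Oxidative phosphorylation had 14 of 25 members lower and 0 higher (median -0.24), among them NDUFA9 at -0.59 and ATP5F1B at -0.53, although ATP5F1B was at -0.02 with median centring (adjusted p = 0.913). The cell cycle list had 17 of 36 lower and 5 higher (median -0.16), with KIF20A at -0.82 and CDC20 at -0.80 but CENPE, a kinetochore motor, at 1.12. The medians of JAK-STAT target genes, oxidative phosphorylation and the cell cycle turned to 0.03, 0.14 and 0.14 with median centring, which moved the median of all genes under shTLR7 to 0.10. Relative to all genes, they stood at -0.07, 0.04 and 0.03. Ribosomal proteins rose, 24 of 26 with 0 lower (median 0.49), with RPS6 at 0.84 and RPS16 at 0.75, although their probes can also bind processed pseudogenes. The type I interferon response had 24 of 36 higher and 2 lower (median 0.36), with SAMD9L at 1.36, IFI27 at 0.92 and XAF1 at 0.89. Of 23 p53 target genes, 17 rose and 2 fell (median 0.32), with GADD45A at 1.14, TP53INP1 at 1.08 and SESN1 at 0.92. Glycolysis and hypoxia had 18 of 28 higher and 2 lower (median 0.42), where ADM, ANKRD37 at 1.15 and BNIP3 at 1.02 are hypoxia-responsive genes rather than glycolytic enzymes. Adjusted over the list alone, the members higher and lower were 0 and 23 for cholesterol, 1 and 22 for MYC, 2 and 9 for JAK-STAT, 0 and 14 for oxidative phosphorylation, 5 and 18 for the cell cycle, 24 and 0 for ribosomal proteins, 25 and 2 for interferon, 18 and 2 for p53 and 19 and 2 for glycolysis. Camera's adjusted p ran from 6.71e-20 for cholesterol to 0.0119 for the cell cycle. With an estimated correlation none of the 9 lists passed (adjusted p = 0.60 for 7 of them, 0.641 for glycolysis and 0.707 for the cell cycle). That setting has little power here, and ribosomal proteins lost their call at an estimated correlation of 0.0244.

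Among genes with a current symbol, those that rose most under shTLR9 included a granule protease, chemokines and a cytokine subunit. GZMB (probe on chromosome 14, 25100236 to 25100295) rose by 1.67 ± 0.11, CCL4 by 1.45 ± 0.14, CXCL13 by 1.20 ± 0.11 and IL23A by 1.15 ± 0.09. IFIT1 (0.91) and MX1 (0.84) are interferon-induced antiviral proteins, and CXCL10 (0.84) is an interferon-induced chemokine. TESC rose by 0.87, PLAC8 by 0.84 and TCL1A, an AKT coactivator, by 0.84. SPP1, which encodes osteopontin (chromosome 4, 88903920 to 88903979), fell to -2.53 ± 0.21. Several of the genes that fell serve sugar metabolism, PFKFB4, a regulator of glycolysis, at -2.11, SLC16A3, a lactate exporter, at -2.06, SLC2A14, a glucose transporter, at -1.96 and ALDOC, an aldolase, at -1.82. The SLC2A14 probe may also bind its close paralog SLC2A3. NUAK2 (-2.02), PLS3 (-1.94, with a knockdown signal not well above background on every array), GNG8 (-1.75) and VASN (-1.73) fell as well. Adjusted p for these 20 genes, TLR9 included, ran from 2.06e-05 to 0.000543. With the authors' series matrix values only GZMB, IFIT1, NUAK2, TLR9, SLC2A14 and VASN of these 20 passed, and SPP1 (adjusted p = 0.0634), PFKFB4 (0.0636), SLC16A3 (0.076), CCL4 (0.0749) and the others kept their sign but not their call. In all, 3725 genes passed, 1619 higher and 2106 lower, and 354 changed at least 1.5-fold, 69 up and 285 down. With median centring the balance turned, to 9666 higher and 3856 lower, and at 1.5-fold to 4203 and 374. On both days, 39 genes were at least 1.5-fold higher, 195 lower and 0 opposite. Genes 1.5-fold the same way on both days moved from 234 to 1179 with the authors' series matrix values and 3488 with median centring. The count moved with the setting: the authors' series matrix values gave 151 genes, median centring 13522 and day as a term 6076. Without shTLR9 day 1 it was 1868, without shTLR9 day 2 it was 713, and without either shTLR7 array it was 6433.

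Glycolysis and hypoxia had the deepest shift of the lists under shTLR9, with 21 of 28 members lower, 0 higher and a median of -0.51, and CA9, a hypoxia-induced carbonic anhydrase, at -1.55. With median centring this list median stood at 0.03, which is -0.19 relative to all genes. Antigen presentation had 18 of 25 lower and 1 higher (median -0.33). Its lowest members were the class II genes HLA-DMA (-0.80), HLA-DPB1 (-0.79) and HLA-DPA1 (-0.73). Whether their probes also bind other class II transcripts was not examined. In cholesterol biosynthesis 14 of 25 were lower and 0 higher (median -0.33), led by FASN (-0.69), SREBF1 (-0.64) and SCD (-0.63), which serve fatty acid synthesis or its control. Lymphocyte trafficking and FOXO1 targets had 7 of 12 lower and 0 higher (median -0.32), with GPR183 at -0.85 and CXCR4 at -0.74. B cell identity had 9 of 20 lower and 0 higher (median -0.21), with POU2AF1 at -1.51, BCL6 at -0.56 and BANK1 at -0.51. B cell receptor signalling had 10 of 23 lower and 0 higher (median -0.22), with FCGR2B at -0.59 and CD22 at -0.48. The ATF4 and amino acid response had 7 of 19 lower and 2 higher (median -0.20), with DDIT4 at -1.25 and VLDLR at -0.69. Immediate early genes had 9 of 22 lower and 1 higher (median -0.12), with IER2 at -0.52, ZFP36 at -0.46 and EGR2 at -0.41. The Toll-like receptor pathway had 7 of 30 lower and 0 higher (median -0.05), with TLR9 itself, whose fall the shRNA was designed to bring about, among them, CD180 at -0.92 and SIGIRR at -0.38. Its median ranked at the 10.6th percentile of random lists, and the list was not tested without TLR9. Of these falling lists, only the trafficking list stayed below 0 with median centring, at -0.08, and it no longer passed (adjusted p = 0.156). The others turned to medians of 0.15 for antigen presentation, 0.15 for cholesterol, 0.29 for B cell identity, 0.33 for B cell receptor signalling, 0.23 for ATF4, 0.12 for immediate early genes and 0.34 for the Toll-like receptor pathway, while the median of all genes moved to 0.22. Relative to all genes, antigen presentation (-0.07), cholesterol (-0.07) and immediate early genes (-0.09) stayed lower, and B cell identity (0.07), B cell receptor signalling (0.12), ATF4 (0.01) and the Toll-like receptor pathway (0.12) did not. With median centring HLA-DMA, HLA-DPB1, HLA-DPA1, FASN, SREBF1, SCD, CXCR4, BANK1, FCGR2B and CD22 stayed below 0 but no longer passed.

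The lists that rose under shTLR9 were ribosomal proteins, interferon, p53, MYC and plasma cell genes. With median centring their medians were larger, at 1.05, 0.53, 0.65, 0.75 and 0.50, but the median of all genes moved to 0.22. Housekeeping genes stood at 0.64 and histones at 0.57 in that setting, so the larger medians add no support. Ribosomal proteins had 13 of 26 higher and 1 lower (median 0.22), with RPS16 at 0.67 and RPS6 at 0.62. The interferon response had 15 of 36 higher and 4 lower (median 0.19), with XAF1 at 0.68. Of the p53 target genes 8 of 23 were higher and 2 lower (median 0.14), led by MDM2 (0.49) and FAS (0.43). MYC targets and ribosome biogenesis had 6 of 31 higher and 0 lower (median 0.12), with GNL3 at 0.48, NOP58 at 0.45 and HSPD1 at 0.42. Plasma cell differentiation had 5 of 20 higher and 1 lower (median 0.12), with ELL2 at 0.48 and CREB3L2 at 0.49 (0.87 on day 1 and 0.11 on day 2) but TENT5C at -1.04. Adjusted over the list alone, the members higher and lower under shTLR9 were 1 and 23 for glycolysis, 1 and 19 for antigen presentation, 0 and 19 for cholesterol, 0 and 7 for trafficking, 0 and 11 for B cell identity, 0 and 14 for B cell receptor signalling, 2 and 8 for ATF4, 1 and 10 for immediate early genes, 0 and 8 for the Toll-like receptor pathway, 16 and 1 for ribosomal proteins, 19 and 5 for interferon, 10 and 3 for p53, 9 and 0 for MYC and 9 and 2 for plasma cells. Camera's adjusted p for the 14 lists ran from 4.80e-15 for glycolysis to 0.0342 for plasma cells. With an estimated correlation none of them passed (adjusted p = 0.358 for 9 of the 14, 0.368 for glycolysis, 0.428 for interferon, 0.449 for cholesterol, 0.575 for ATF4 and 0.617 for MYC).

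The 2 knockdowns were then set against each other, shTLR9 minus shTLR7. A probe's dye effect cancels there if it is the same on every array, but bias that differs between arrays does not. Among genes with a current symbol the largest differences included ADM (-3.72 ± 0.15), SLC16A3 (-3.45 ± 0.27), HILPDA, a lipid droplet protein (-3.01), H19 (-2.82), GNG8 (-2.81), DHDH (-2.47), PFKFB4 (-2.43), SERPINA9 (-2.30) and ANKRD37 (-2.29). KRT80 was lower under shTLR9 too, but its control was not well above background, so the size of its difference is uncertain. GZMB was higher under shTLR9 by 3.47 ± 0.15, CCL4 by 1.93, MRTO4, a ribosome assembly factor, by 1.49, GZMH by 1.46, DHCR7 by 1.39, ADTRP by 1.38, SQLE by 1.37, ACAT2 by 1.36, TNFAIP2 by 1.34 and FADS1, a fatty acid desaturase, by 1.31. GZMH and GZMB are paralogs, and the GZMH probe can bind both. ADM, SLC16A3, HILPDA, GNG8, ANKRD37, H19 and SERPINA9 rose under shTLR7 and fell under shTLR9, and GZMB, CCL4, GZMH, ADTRP and TNFAIP2 the reverse. Adjusted p ran from 1.09e-05 to 0.00048. In all, 3605 genes passed, 1478 higher and 2127 lower under shTLR9, and 1039 differed at least 1.5-fold, 288 higher and 751 lower. With median centring the balance turned, to 2471 higher and 1183 lower, and at 1.5-fold to 1613 and 733. No gene passed with the authors' series matrix values in limma, where 5470 had an unadjusted p under 0.05, and all of the 1039 kept their sign. Without shTLR9 day 1 the count was 1798, without shTLR9 day 2 it was 2111, without shTLR7 day 2 it was 5471, and with day as a term it was 5753.

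Between the knockdowns, 21 of 28 glycolysis and hypoxia genes were lower under shTLR9 and 0 higher (median difference -0.84). Antigen presentation had 11 of 25 lower and 0 higher (median -0.22, HLA-DOB at -0.96), ribosomal proteins 4 of 26 lower and 0 higher (median -0.22, RPL13 at -0.39) and lymphocyte trafficking 4 of 12 lower and 1 higher (median -0.19, ITGB7 at -0.80). The ATF4 and amino acid response had 7 of 19 lower and 1 higher (median -0.17, DDIT3 at -1.72), p53 target genes 5 of 23 lower and 2 higher (median -0.26, GADD45A at -1.001) and the interferon response 10 of 36 lower and 1 higher (median -0.16, IFI27 at -1.13). The p53 median turned to 0.01 with median centring, and the lists of interferon (adjusted p = 0.373), ATF4 (0.301), trafficking (0.325), antigen presentation (0.228) and ribosomal proteins (0.456) no longer passed. Cholesterol biosynthesis had 20 of 25 higher and 0 lower (median 0.72), MYC targets 21 of 31 higher and 0 lower (median 0.45, NOP16 at 0.81) and oxidative phosphorylation 8 of 25 higher and 0 lower (median 0.23, ATP5F1A at 0.61). The cell cycle had 11 of 36 higher and 1 lower (median 0.25), with RRM2 at 0.94 but CENPE at -1.07. Plasma cell differentiation had 5 of 20 higher and 1 lower (median 0.16), with CD38 at 1.01 but TENT5C at -1.24. Adjusted over the list alone, the members higher and lower were 0 and 23 for glycolysis, 0 and 11 for antigen presentation, 0 and 8 for ribosomal proteins, 2 and 5 for trafficking, 1 and 7 for ATF4, 2 and 8 for p53, 2 and 12 for interferon, 21 and 0 for cholesterol, 27 and 0 for MYC, 10 and 0 for oxidative phosphorylation, 16 and 2 for the cell cycle and 8 and 2 for plasma cells. Camera's adjusted p ran from 1.57e-17 for cholesterol to 0.0169 for trafficking. None of the 12 lists passed with an estimated correlation (adjusted p = 0.434 for 9 of them, 0.452 for the cell cycle, 0.522 for ATF4 and 0.522 for interferon). The low power of that setting holds here too, as does the gap between the preset and the estimated correlations.

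**Figure D2:**
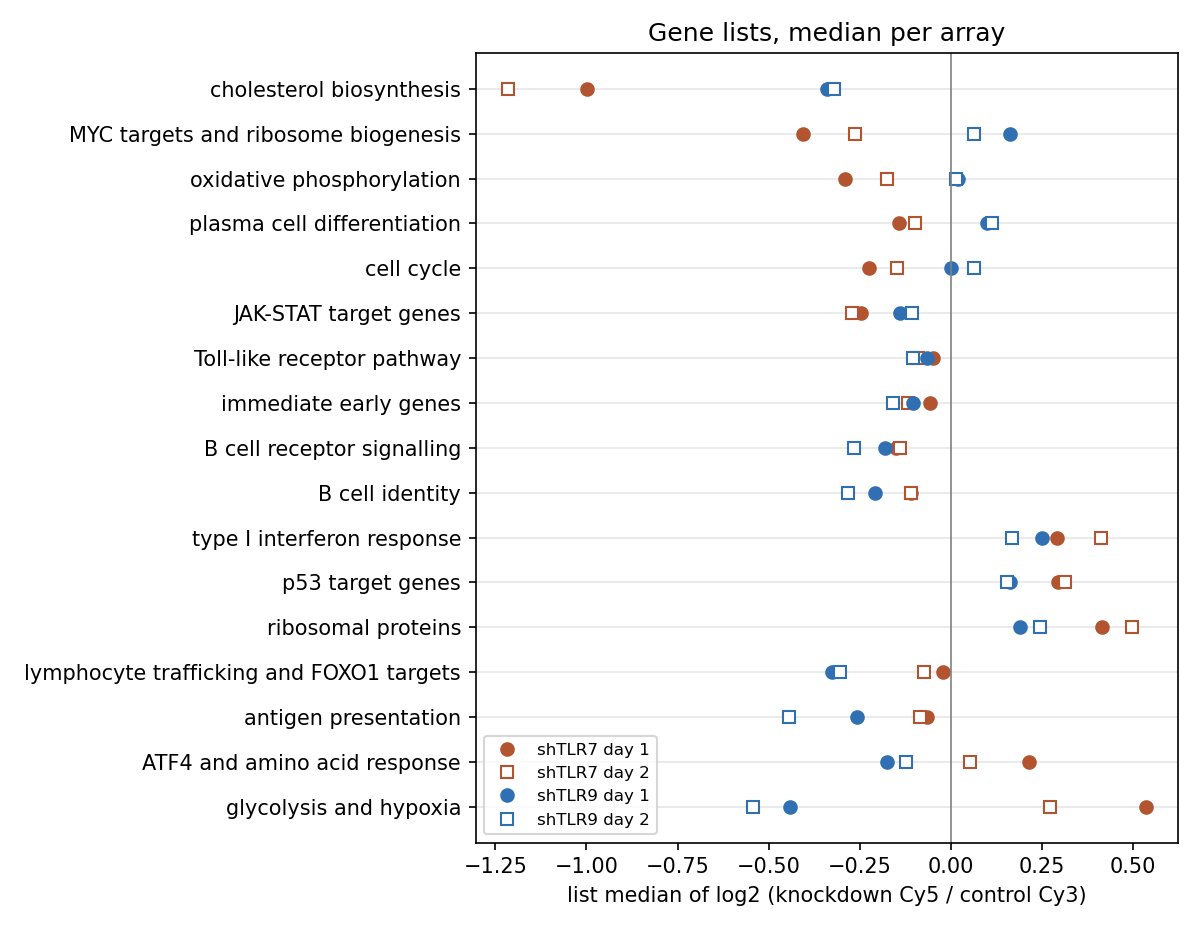
Median log2 ratio (horizontal axis) of the 17 gene lists that passed camera at its preset correlation in at least 1 contrast, on each of the 4 arrays. Circles are day 1 and open squares day 2. Cholesterol biosynthesis lies at -0.997 and -1.22 on the shTLR7 arrays and at -0.34 and -0.32 on the shTLR9 arrays, and glycolysis and hypoxia at 0.53 and 0.27 against -0.44 and -0.54.

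NF-kB target genes, which are only some of the transcripts downstream of MYD88, passed as a list in no contrast in the setting used here. Camera gave them an adjusted p of 0.610 under shTLR7, 0.607 under shTLR9 and 0.570 for the difference. They passed under shTLR9 when its day 2 array was left out, and with median centring they passed under shTLR9 (median 0.56, adjusted p = 0.000184) and in the difference (0.25, adjusted p = 0.00281). Members moved both ways. Of 36, 9 rose and 12 fell under shTLR7 (10 and 14 adjusted over the list alone), with BIRC3 at 0.84 and LTB at 0.83 but TNF at -1.01. Under shTLR9, 7 rose and 4 fell (7 and 5 over the list alone), with CCL3 at 0.81 and TNFAIP2 at 0.80. In the Toll-like receptor pathway under shTLR7, 7 of 30 rose and 11 fell (9 and 12 over the list alone, adjusted p = 0.337), among them IRAK1 at -0.56 and CD180 at -0.54, neither of which passed with median centring. Other lists passed in none of the 3 contrasts in that setting. Their medians under shTLR7 and shTLR9 were -0.08 and 0.04 for the unfolded protein response, 0.07 and -0.13 for the BCL2 family with caspase inhibitors (which passed in the difference when dim probes were kept and, with adjusted p = 0.0139, without shTLR7 day 1), 0.03 and -0.03 for histones, 0.01 and 0.01 for the RNA interference machinery and -0.08 and -0.05 for housekeeping genes. With median centring housekeeping genes (0.64), histones (0.57), the unfolded protein response (0.63) and the RNA interference machinery (0.53) passed upwards under shTLR9, as did the cell cycle (0.60) and oxidative phosphorylation (0.69). In the difference, JAK-STAT target genes (0.29), the unfolded protein response (0.46), the RNA interference machinery (0.35) and housekeeping genes (0.35) passed upwards with it as well. Markers of other cell types did not pass as lists in that setting either. Their medians were 0.01 and -0.01 for T and NK cells, a list that holds GZMB, 0.14 and 0.02 for myeloid cells, and -0.02 and -0.12 for epithelial cells and fibroblasts. Of 7 myeloid markers, 3 were higher and 0 lower under shTLR7. The myeloid list passed in the difference with median centring (adjusted p = 0.0136) and under shTLR7 without its day 2 array (adjusted p = 0.0251), and the epithelial and fibroblast list passed in the difference with the authors' series matrix values.

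NUAK2 and POU2AF1 fell under both shRNAs, with means over all 4 arrays of -1.92 ± 0.10 and -1.85 ± 0.06. The size for NUAK2 is uncertain, since its knockdown signal was not well above background on every array. PLS3 fell under both as well, to levels near background. CYP1A1 was at 1.56 ± 0.05 and PLAC8 at 1.05 ± 0.05. The mean of both shRNAs over control passed for 7985 genes, 4122 higher and 3863 lower, of which 353 changed at least 1.5-fold. Median centring raised this count to 13584, with 10147 higher and 3437 lower, the authors' series matrix values lowered it to 4955, and it was 4789 without shTLR9 day 2. On all 4 arrays, 17 genes were at least 1.5-fold higher and 45 lower. Calls under the separate shRNAs were the same way for 806 genes higher and 961 lower, where independent lists would share 306 and 354. They were opposite for 242 and 95 genes, where independent lists would share 398 and 272. Independence is a weak baseline here, since both tests use the same fitted variance of a gene. A probe's dye effect that is the same on every array would also favour calls the same way. If both arrays of a day had 1 control RNA, chance alone would make their ratios correlate. In 100 simulations of unchanged arrays this gave a covariance of 0.0105, against an observed 0.0107 on day 1 and 0.0372 on day 2. The simulated control and knockdown channels had the same spread. That choice alone sets r at 0.50 and the same-sign share near 66.6%, and the simulated covariance rests on it too. The observed r of 0.17 on day 1 and 0.48 on day 2 therefore cannot be weighed against 0.50. Arrays of different days, which have no control in common if each day had its own, correlated between the shRNAs with r = 0.21 and 0.36. For the means over days the covariance was 0.0218 against a simulated 0.00526, r was 0.345 and 63.3% of genes had the same sign. Across genes, the Cy3 signals of same-day arrays differed with an SD of 0.192 on day 1 and 0.156 on day 2. Those of different days differed with an SD of 0.124 to 0.225, so controls were no more alike within a day. The control could not be split, so part of the overlap may come from it.

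**Figure D3:**
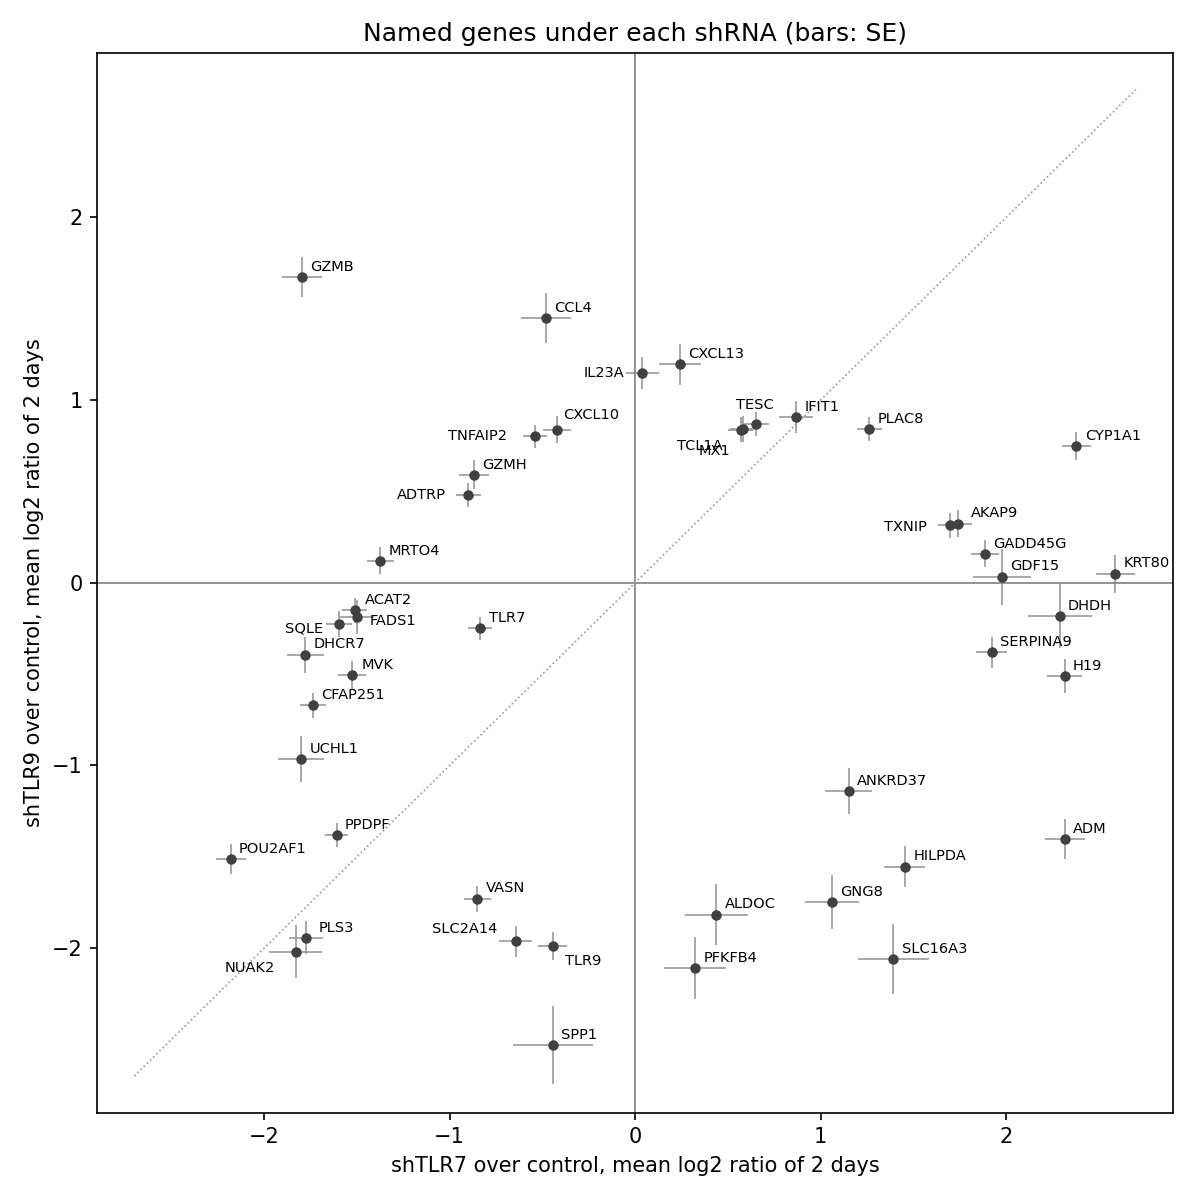
Mean log2 ratio over the 2 days under shTLR7 (horizontal axis) and shTLR9 (vertical axis) of the 46 named genes. Each point is a gene, bars are the SE of the fit, and the dotted line marks equal values. POU2AF1, NUAK2 and PLS3 lie low on both axes, ADM and SLC16A3 at the lower right, and GZMB at the upper left.

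Day 2 minus day 1 gives the change in the log ratio with time over both shRNAs. CTSZ, a lysosomal protease, changed most, by -2.47 ± 0.25 (adjusted p = 0.0121). Among genes with a current symbol, CTSZ was followed downwards by ZC3H7B (-1.12), NPM3 (-1.06), U2AF2 (-1.04) and LSM14B (-0.90). EML2 rose by 1.29, ENSA by 1.28, TMED9 by 1.17, PRPS1 by 1.15 and PRKAG1 by 0.98. The probes of LSM14B differed, at -1.69 and -0.11. In all 44 genes passed, 21 upwards and 23 downwards, and 37 changed at least 1.5-fold. In 40 of the 44 the control's Cy3 signal changed the other way on both arrays, which choosing genes by a change of Cy5 over Cy3 favours. For CTSZ the Cy3 level rose by 1.45 from day 1 to day 2, while Cy5 fell by 1.69 under shTLR7 and by 0.35 under shTLR9. No gene passed in limma without background subtraction, where 2428 had an unadjusted p under 0.05, or with the authors' series matrix values, where 1415 had.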

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

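The tests of a probe dye effect and of hypoxia-responsive genes in general, on the glycolysis and hypoxia list, were chosen only after the result was seen, as was the remark on lasting control differences. The other tests were set before their result was seen.

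The knockdowns differed in 3605 genes, and 12 gene lists differed between them. The median differences (shTLR9 minus shTLR7, log2) were 0.72 for cholesterol biosynthesis, 0.45 for MYC targets and ribosome biogenesis, 0.25 for the cell cycle, 0.23 for oxidative phosphorylation, 0.16 for plasma cell differentiation, -0.16 for the type I interferon response, -0.17 for the ATF4 and amino acid response, -0.19 for lymphocyte trafficking, -0.22 for antigen presentation, -0.22 for ribosomal proteins, -0.26 for p53 target genes and -0.84 for glycolysis and hypoxia. Each passed limma's camera at its preset correlation, and none did with an estimated correlation, a setting with 2 residual degrees of freedom and little power.

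Most of the genes named here also differed between the shRNAs past the threshold. In cholesterol biosynthesis these were DHCR7 (1.39), SQLE (1.37), ACAT2 (1.36), MVK (1.02), FASN (0.81), SCD (0.67) and SREBF1 (0.55). In glycolysis and hypoxia these were BNIP3 (-1.69), CA9 (-1.996), ALDOC (-2.25), ANKRD37 (-2.29), PFKFB4 (-2.43) and ADM (-3.72). In MYC targets these were MRTO4 (1.49), NOP16 (0.81), EIF4A1 (0.56), HSPD1 (0.54) and GNL3 (0.45). In the cell cycle list these were RRM2 (0.94), CDC20 (0.72), KIF20A (0.61) and CENPE (-1.07). In p53 target genes these were SESN1 (-0.64), TP53INP1 (-0.65), BBC3 (-0.80) and GADD45A (-1.001). In oxidative phosphorylation these were ATP5F1A (0.61), NDUFA9 (0.59), ATP5MC1 (0.58) and ATP5F1B (0.48). In ribosomal proteins these were RPL11 (-0.38) and RPL13 (-0.39). In antigen presentation these were HLA-DMA (-0.77), HLA-DPA1 (-0.80), HLA-DPB1 (-0.89) and HLA-DOB (-0.96). In the interferon response these were SAMD9L (-0.75) and IFI27 (-1.13). In NF-kB and JAK-STAT target genes these were CCL4 (1.93), TNFAIP2 (1.34), TNF (0.77), OSM (0.59), CCL3 (0.58), SOCS3 (0.53), BIRC3 (-0.32), LTB (-0.62) and IL10 (-0.95). In the Toll-like receptor pathway these were TLR7 (0.59), IRAK1 (0.39), CD180 (-0.38) and TLR9 (-1.55). In B cell identity and receptor signalling these were POU2AF1 (0.67), CD22 (-0.35), FCGR2B (-0.48), BANK1 (-0.86) and BCL6 (-1.12). In plasma cell differentiation and the ATF4 response these were CD38 (1.01), VLDLR (-1.14), TENT5C (-1.24), DDIT4 (-1.63) and DDIT3 (-1.72). In lymphocyte trafficking and immediate early genes these were IER2 (-0.36), EGR2 (-0.63), CXCR4 (-0.76) and ITGB7 (-0.80). Among the remaining named genes, GZMB (3.47), GZMH (1.46), ADTRP (1.38), FADS1 (1.31), CXCL10 (1.26), IL23A (1.11), CFAP251 (1.07), CXCL13 (0.96) and UCHL1 (0.83) were higher under shTLR9. Lower under shTLR9 were PLAC8 (-0.42), VASN (-0.88), SLC2A14 (-1.32), TXNIP (-1.39), AKAP9 (-1.42), CYP1A1 (-1.63), GADD45G (-1.73), GDF15 (-1.94), SPP1 (-2.09), SERPINA9 (-2.30), DHDH (-2.47), KRT80 (-2.54, of uncertain size because the control was not well above background), GNG8 (-2.81), H19 (-2.82), HILPDA (-3.01) and SLC16A3 (-3.45).

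Spike-in RNA, added to the labelled samples and used in no comparison, had medians above 0 on every array. Over 10 spike-in probes in 320 spots an array, the median log2 ratio after loess was 0.70 on shTLR7 day 1, 0.39 on shTLR7 day 2, 0.29 on shTLR9 day 1 and 0.13 on shTLR9 day 2. The loess fit gave control spots no weight, so these medians were not forced to 0. The spike-in intercepts in the file headers, taken to log2, were 0.80, 0.49, 0.33 and 0.21.

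Glycolysis and hypoxia genes differed between the 2 shRNAs, with opposite signs after loess. A dye effect of the probes that was the same on every array would give the list 1 sign on all of them. The list median was at least 0.27 on the shTLR7 arrays and at most -0.44 on the shTLR9 arrays. These signs are the pattern itself, so they are no separate test of it. Probe GC content or the normalization would bring the difference near 0. It was -0.85 with GC correction, -0.64 with median centring and -0.83 with scaling between arrays. Without background subtraction it was -0.88, and with the authors' series matrix values -0.95. Over 11 settings it lay between -1.06 and -0.64. These also count the main fit, day as a term, filters and the brightest probe, which do not test this explanation. The opposite signs against the control do depend on the normalization, since with median centring the shTLR9 median was 0.03, or -0.19 relative to all genes. A difference in oxygen or culture density that acts through hypoxia-responsive genes in general remains open, since hypoxia-responsive genes outside glycolysis differed by a median of -1.30, against -0.41 for glycolytic enzymes.

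A set of 62 genes was at least 1.5-fold the same way on all 4 arrays. Chance deviation of the control RNA of a single day is argued against, since 78 of the 80 genes chosen on day 1 (97.5%, exact interval 91.3% to 99.7%) had the same sign on both day 2 arrays. A dye effect of single probes stays open. Among genes with a current symbol whose first probe was at least 1.5-fold the same way on all 4 arrays, 25 had a second probe. These 25 genes need not be among the 62, which were chosen on the average of their probes. The second probe had the sign of the first in 23 of 25 (92%), with an exact lower bound of 74.0% that missed the 75% set in advance. A lasting difference of the shControl cells from both knockdown populations cannot be told apart from an effect of either knockdown, for these 62 genes, because the series has no array with a second control. The biological explanation, a change that both knockdowns bring about, is likewise untested.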

How the results depend on the processing

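TLR7 under shTLR7 (-0.84) and TLR9 under shTLR9 (-1.99) kept direction and significance in every alternative, between -0.66 and -1.34 and between -1.39 and -2.14. Leaving out 1 array in turn, TLR7 lay between -0.89 and -0.78 and TLR9 between -2.10 and -1.88, where the lone array of an shRNA was assumed to vary like the others. Counts of genes then ran from 6750 to 7330 for shTLR7, 713 to 6433 for shTLR9, 4789 to 9190 for the mean of both and 1798 to 5471 for shTLR9 minus shTLR7, and counts of lists from 8 to 11, 12 to 16 and 11 to 14. With fewer arrays the fit rests on fewer residual degrees of freedom.

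At least 1.5-fold, the counts for shTLR7, shTLR9, the mean and the difference were 1132, 354, 353 and 1039. At least 2-fold on both days, 131 genes stood under shTLR7 and 41 under shTLR9. Without background subtraction limma called 0 genes for the day (2428 at unadjusted p under 0.05). With Agilent's processed log ratio the counts were 4883, 151, 4983, 0 (5469 at unadjusted p under 0.05) and, for the day, 0 (1418), and 2671 and 1177 genes were 1.5-fold on both days. With the authors' series matrix values they were 4862, 151, 4955, 0 (5470 at unadjusted p under 0.05) and 0 (1415), with 2673 and 1179. An intensity trend gave 132 genes for the day and GC correction, added after seeing the data, 11. Day as a term gave 6076 for shTLR9 and 5753 for the difference. With an estimated correlation, where it tests on 2 residual degrees of freedom, camera called 0, 0 and 0 lists (lowest adjusted p 0.60, 0.358 and 0.434). The cause was not tested for any of these.

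Median centring gave 13522 genes for shTLR9, 13584 for the mean, 102 for the day, and 1310 and 3488 on both days. The higher share of calls moved from 52.9% to 88.7% for shTLR7, 43.5% to 71.5% for shTLR9, 51.6% to 74.7% for the mean, 41.0% to 67.6% for the difference and 47.7% to 76.5% for the day, and for shTLR9 to 30.5% with the matrix values. Median centring leaves the log ratio tied to intensity (Spearman 0.15, 0.66, 0.87 and 0.84 on the 4 arrays, against -0.04, -0.04, -0.02 and -0.03 with loess). It turned TLR7 (0.036), SIGIRR (0.21), BCL6 (0.039), ATF5 (0.10), IER2 (0.13), ZFP36 (0.20) and EGR2 (0.086) under shTLR9, all of them still 0.007 to 0.18 below the median of all genes. Among lists past the threshold in either setting it turned JAK-STAT target genes (0.030), the cell cycle (0.14) and oxidative phosphorylation (0.14) under shTLR7. Under shTLR9 it turned the Toll-like receptor pathway (0.34), B cell receptor signalling (0.33), B cell identity (0.29), ATF4 (0.23), cholesterol (0.15), glycolysis and hypoxia (0.028), immediate early genes (0.12), antigen presentation (0.15), histones (0.57) and housekeeping genes (0.64). In the difference it turned NF-kB target genes (0.25) and p53 target genes (0.013). Other lists, which passed in neither setting, crossed 0 too. Whether the tie to intensity accounts for each turn was not tested.

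Of the other comparisons with an alternative, 2052 of genes and 1072 of lists were unchanged, 263 and 57 weaker and 4 and 26 stronger. A slide block was not run, since there is 1 slide, and the day contrast has no leave-one-out, since no residual degree of freedom is left. The labels carry no replicate numbers. They pair arrays by day, and day as a term above is that fit. Cy5 signals well above background for 66.3% to 78.9% of spots limit what can be said of dim genes.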

Other observations

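The short lists described here were written after values had been seen, so their counts describe and do not test them. Of the hypotheses on cholesterol, both predictions were written before their test was run.

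Metallothioneins, small proteins that bind zinc and copper, moved opposite ways under the 2 shRNAs. Under shTLR7, 7 of 9 measured members were higher and 0 lower (median 0.39), and under shTLR9 all 9 were lower (median -0.81), a median difference of -1.24. MT2A stood at 0.75 and -0.81. MT1E was lower under shTLR9 by -1.45. Their probes can bind several members, so the 9 genes do not count as 9 observations. Chemokines and cytokines had 10 of 22 members higher under shTLR9 than under shTLR7 and 2 lower (median difference 0.30). CXCL9, an interferon-induced chemokine, was higher by 0.65, CCL17 by 0.76 and IL6 by 0.65. IL15 was higher under both shRNAs, at 0.60 and 0.83. Genes whose mRNAs start with a terminal oligopyrimidine tract, and hosts of small nucleolar RNAs, had 9 of 15 members higher under shTLR7 and 0 lower (median 0.22), with the elongation factor EEF2 at 0.80 and TPT1 at 0.45, and under shTLR9 0 of 15 passed in limma either way (median 0.04). Hypoxia-responsive genes outside glycolysis had 15 of 18 members higher under shTLR7 (median 0.65) and 16 lower under shTLR9 (median -0.64). Glycolytic enzymes had 7 of 17 higher and 2 lower under shTLR7 (median 0.21), and 0 higher and 11 lower under shTLR9 (median -0.33).

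Cholesterol biosynthesis genes were lower under shTLR7. An excess of cellular sterol could lower them, and it would raise liver X receptor targets. Their median under shTLR7 was 0.00668 over 9 genes (interquartile range -0.08 to 0.53), neither above the 0.2 nor at or below the 0 set in advance. MYLIP rose by 0.82 and APOC1 by 1.13 but LPCAT3 fell to -0.46. Lower activity of the sterol-regulated transcription factors as a whole could do the same and would lower fatty acid synthesis genes. The median of those outside the cholesterol list was -0.21 on day 1 and -0.29 on day 2, between the -0.1 and -0.3 set in advance. FASN (-1.498), SCD (-1.30) and SREBF1 (-1.19), which that list holds and this test left out, fell further. Both hypotheses stay open.

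For the 44 genes that changed with the day, the control's Cy3 change was a median of 50.4% of the change in the log ratio, and at least 50% of it in 23 genes and under 25% in 6. The change in Cy5 was a median of 68.0% under shTLR7 and 29.2% under shTLR9. The genes were chosen for a change of Cy5 over Cy3, which favours a share in both channels. For this reason 2 tests of control against knockdown cells, written after the values were seen and run once, were dropped. The first had met its prediction and the second had left the matter open. The Cy3 level of U2AF2 differed by 2.26 between the 2 arrays of day 1.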
